A study of Mus musculus with 24 samples.

How the data were processed

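Total RNA was extracted with a column kit from left ventricle, skeletal muscle and kidney of C57BL6/J mice and sequenced after ribosomal RNA depletion. Per the labels, reads were aligned to GRCm38.p6 with STAR 2.7.6a and quantified with StringTie 2.1.1. The deposited table holds gene counts for 55401 genes in 24 libraries, and the values are whole numbers. Neither the annotation release, nor the strand setting, nor how StringTie gave counts is stated. Of the gene identifiers 54349 matched GENCODE release M21, which gave coordinates, exon lengths and gene types, 110 symbols occurred more than once, and 140 genes had 0 counts in every library.

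The labels do not say which skeletal muscle or which part of the kidney was sampled, or whether it was the same in every mouse. Groups came from the labels: 2 ages, 2 sexes and 3 tissues, with 2 mice per age and sex. Age and sex were tested within each tissue by edgeR 4.0.16 quasi-likelihood F-tests (R 4.3.3) on 8 libraries, in a fit with additive terms for sex and age that left 5 residual degrees of freedom. Libraries were normalised by TMM, genes with low counts were removed by filterByExpr on the age and sex groups, and p-values were two-sided and adjusted by Benjamini-Hochberg with a threshold of 0.05. The interaction of age and sex came from a fit with that term added. Whether the age change differed between tissues was tested by an F-test on the 3 tissue-specific age terms in a fit of all 24 libraries without a term for the mouse. The mouse as a replicate block was an alternative. CPM are counts scaled to the TMM-normalised library size unless given as without normalisation, and errors are SD for levels and SE for log2 changes.

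Gene lists, 38 in all with 754 entries of which 1 symbol was not found (Ahsp), were written beforehand. In left ventricle 26, in skeletal muscle 26 and in kidney 29 were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation between genes of 0.01), adjusted over the lists of a tissue. Camera compares a list with the other genes. Fry asks whether the members of a list move, on balance, 1 way, and makes no such comparison. Every call was repeated with the correlation estimated from the data. Members were also adjusted over the list alone.

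Named genes were chosen by a rule. For age these were the 10 largest rises and falls past the threshold, with a mean of at least 1 CPM and the same sign in females and males. For sex they were the 6 largest each way on autosomes, where the same sign was read as the same sign at both ages, and for the interaction the 5 largest each way. For the comparison of tissues they were the 8 genes with the smallest p. Of the genes that the rule named, 2 are not reported here. Predicted gene models and immunoglobulin segments were left out of the naming and counted as groups. Where fewer than 4 genes passed, the 5 with the smallest p are given as values. From each list up to 4 members past the threshold were named, or up to 2 as values, and Xist, the Y-linked genes, Cdkn2a, Cdkn1a and 2 markers per tissue were named in any case. Gm42878 beside Adam1a, the remaining interaction calls of left ventricle, the levels of Umod and Slc34a1 beside Kap, Myh6 in skeletal muscle, Myh4 in left ventricle and the genes shared between tissues were singled out after their values were seen.

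The design, the lists, the naming rule and the first set of alternatives were fixed before the data were examined. The alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, no low-count filter, a filter of 1 CPM in 4 libraries, mitochondrially encoded genes left out, no covariate, all 24 libraries in a single fit and leaving out each mouse in turn. Other alternatives were chosen after seeing the data: testing genes above the 95th percentile of olfactory receptor genes alone (mean CPM per exon kilobase, set per tissue), and leaving out genes listed at 0 in a library while another library of the tissue had at least 100 counts. Medians of the lists under 4 scalings, and 2 collecting duct lists, were also added after seeing the data. Under these scalings the median log2 change of all genes moved by -0.03 to 0.02.

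The tests were tested on simulated data with the means, dispersions and library sizes of each tissue, with 100 genes changed 2-fold and 100 changed 4-fold among those with a mean of at least 50 counts, and 5 lists shifted by 1.5-fold. For age and sex 61 to 79% of the 2-fold and 97 to 100% of the 4-fold changes were recovered. For the interaction these were 6 to 21% and 54 to 73%, and for the comparison of tissues 51 and 92%. False calls exceeded 5% of the calls in all 10 comparisons. They were 20 of 190 for age and 19 of 196 for sex in left ventricle, 10 of 178 and 16 of 177 in skeletal muscle, and 16 of 191 and 12 of 185 in kidney. For the interaction they were 9 of 87, 12 of 72 and 19 of 113 in the same order of tissues, and for the comparison of tissues 9 of 152. Genes were drawn independently of each other, so these data do not show how camera behaves where genes vary together. All 5 shifted lists were called in each tissue, with 0 false lists by camera, while other splits of the real mice gave a median of 9, 9 and 12 called lists in left ventricle, skeletal muscle and kidney. The shift of 1.5-fold was larger than the median change of most called lists, so recovery of smaller shifts was not tested. Single values were compared by exact permutation tests. Coordinates are those of GRCm38.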

Results

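Total RNA depleted of ribosomal RNA was sequenced from the left ventricle, skeletal muscle and kidney of 8 C57BL6/J mice, 4 aged 16.5 weeks and 4 aged 86 weeks, with 2 females and 2 males at each age. The mouse names recur in all 3 tissues, so the 24 libraries form 6 groups of 4 mice. Replicates carry the mouse numbers, which are 14 and 15 (females) and 19 and 20 (males) at 16.5 weeks, and 11 and 12 (females) and 14 and 17 (males) at 86 weeks. Total counts ran from 52602585 in left ventricle 86-week replicate 17 to 103797551 in skeletal muscle 86-week replicate 12. Group means at 16.5 and 86 weeks were 76.1 ± 6.89 and 75.0 ± 16.99 M counts in left ventricle and 77.3 ± 11.9 and 83.3 ± 22.3 M counts in skeletal muscle (mean ± SD, n = 4). In kidney they were 68.7 ± 7.10 and 71.3 ± 9.58 M counts. Tissue markers were highest in the tissue of their label, with traces in single libraries of the others. Myh6, the alpha cardiac myosin heavy chain, had 37913 ± 4567 CPM in female and 38457 ± 5885 CPM in male left ventricle against 6.54 ± 2.00 CPM in female and 78.5 ± 149 CPM in male skeletal muscle (n = 4). There 86-week replicate 17 had 302 CPM and the other 3 males at most 4.57 CPM. Umod, the uromodulin of the loop of Henle, had 2286 ± 375 CPM in female and 1744 ± 235 CPM in male kidney. It had 1.09 ± 0.125 CPM in female and 3.27 ± 2.99 CPM in male left ventricle, where 16.5-week replicate 20 had 7.67 CPM, and up to 15.5 CPM in male skeletal muscle, in 16.5-week replicate 19. From 16.5 to 86 weeks Myh4, the fast myosin IIb heavy chain, went from 97177 ± 6516 to 88000.0 ± 7626 CPM and the muscle creatine kinase gene Ckm from 7727 ± 1102 to 6640.4 ± 1459 CPM in skeletal muscle, and neither passed the test. Nor did the natriuretic peptide gene Nppa in left ventricle, from 28.7 ± 13.0 to 62.3 ± 42.4 CPM (1.07 ± 0.43 log2 units, SE, and 0.68 ± 0.40 without 86-week replicate 11 and 0.61 ± 0.52 without 86-week replicate 14), or the phosphate transporter gene Slc34a1 in kidney, from 2556 ± 547 to 2383 ± 887 CPM. Xist, the RNA that silences an X chromosome, was at 413 ± 38.2 CPM in females and 2.75 ± 1.72 CPM in males in left ventricle, and Ddx3y, a Y-linked RNA helicase gene, at 0.0271 ± 0.0542 CPM in female and 64.3 ± 4.63 CPM in male kidney (n = 4 per sex). The Y-linked genes Eif2s3y, Kdm5d and Uty reached 36.7 ± 4.55, 25.5 ± 3.19 and 27.5 ± 1.95 CPM in male left ventricle. Olfactory receptor genes, most of which these tissues are not known to use, had counts as well. Of these 1117 genes 99.5 ± 0.320% had at least 1 count per library, and together they took 602 ± 138 CPM without normalisation (mean ± SD, n = 24).

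The first question was how the left ventricle of aged mice differed from that of young adults. Ano5, an anoctamin membrane protein gene mutated in limb-girdle muscular dystrophy, rose from 4.81 ± 1.70 to 17.6 ± 2.01 CPM (log2 change 1.92 ± 0.18, SE, n = 4 per age). Amy1, the salivary-type amylase, rose from 8.24 ± 1.07 to 24.1 ± 1.97 CPM (1.55 ± 0.12), and Edn3, an endothelin peptide, rose from 2.57 ± 0.258 to 7.55 ± 1.55 CPM (1.56 ± 0.16). Myot, the Z-disc protein myotilin, rose by 1.35 ± 0.16 log2 units, Cds1, an enzyme of phospholipid synthesis, by 1.31 ± 0.13, and Efemp1, the matrix glycoprotein fibulin-3, by 1.24 ± 0.15. Also among the 10 largest rises were Cd209f, a C-type lectin receptor (1.62 ± 0.18), Sh3gl2, an endophilin of membrane uptake (1.45 ± 0.21), the cytochrome P450 gene Cyp2b10 (1.33 ± 0.20, and 1.43 ± 0.23 without 16.5-week replicate 15) and the metalloproteinase gene Adam1a (1.43 ± 0.21). The span of Adam1a overlaps that of the predicted gene Gm42878, whose level went from 5.37 ± 0.677 to 1.43 ± 2.29 CPM while that of Adam1a went from 4.26 ± 0.497 to 11.5 ± 4.22 CPM. Whether the quantification moved reads between these genes was not tested, and leaving out mice cannot show it. The glutamine transporter gene Slc38a1 fell by 0.73 on the log2 scale (SE 0.12) and Ndrg4, a member of the NDRG family, by 0.72 (SE 0.11).

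In the left ventricle edgeR called 33 of 44546 genes at an adjusted p under 0.05, 30 higher and 3 lower at 86 weeks. Ano5 (ENSMUSG00000055489.8, chromosome 7, 51511029 to 51598709 of GRCm38) had an adjusted p of 5.71e-05, Amy1 (ENSMUSG00000074264.12, chromosome 3, 113555710 to 113606699) of 9.16e-06 and Edn3 (ENSMUSG00000027524.9, chromosome 2, 174760619 to 174784042) of 1.43e-04. The 10 risen genes named above passed in all 8 fits that each left out 1 mouse, while Slc38a1 and Ndrg4 passed in 3 each (highest adjusted p 0.232 and 0.142). Without 86-week replicate 17 the count was 117, with DESeq2 it was 73 and without a low-count filter it was 18.

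In the aged left ventricle camera placed lists of complement, macrophage and stress genes higher than other genes. C3, the central complement protein, rose by 1.22 ± 0.19 log2 units (adjusted p = 0.00984, passing in 5 of the 8 fits that each left out 1 mouse, and 1.45 ± 0.13 without 86-week replicate 17), 8 of the 14 members rose when adjusted over the list alone, and all 14 had positive changes. The complement median was 0.48 (camera adjusted p = 5.39e-10, and adjusted p = 0.360 with an estimated correlation). Among 12 cardiac stress and fetal genes, Edn3 rose over all genes tested and 7 rose when adjusted over the list alone. The stress gene median was 0.47 (camera adjusted p = 3.17e-05, and adjusted p = 0.360 with an estimated correlation). None of 22 macrophage markers passed over all genes in edgeR, 8 rose when adjusted over the list alone, and the lysozyme gene Lyz2 was at 0.55 ± 0.15 (0.72 ± 0.10 without 86-week replicate 17) and the lysosomal glycoprotein gene Gpnmb at 0.54 ± 0.16. The macrophage median was 0.37 (camera adjusted p = 2.65e-09, and adjusted p = 0.486 with an estimated correlation). The chemokine gene Ccl8 rose by 2.07 ± 0.34 (adjusted p = 0.0199, passing in 3 of the 8 fits), 1 of 18 senescence and secreted senescence factors over all genes and 1 of 2 when adjusted over the list alone. The senescence median was 0.11 (camera adjusted p = 0.0198, and adjusted p = 0.672 with an estimated correlation). The senescence call was lost without 16.5-week replicates 14 (adjusted p = 0.103) and 15 (0.126), and 86-week replicates 11 (0.112), 12 (0.0954) and 14 (0.195). In MHC class II presentation 0 of 10 members passed either way, with Ciita, its transcriptional regulator, at 0.35 ± 0.13. The MHC class II median was 0.30 (camera adjusted p = 0.0137, and adjusted p = 0.672 with an estimated correlation). The MHC class II call was lost without 16.5-week replicate 15 (adjusted p = 0.197) and 86-week replicates 12 (0.510) and 14 (0.195). Schwann cell and nerve markers had 0 of 14 members over all genes and 1 adjusted over the list alone, with the myelin gene Mal at 0.52 ± 0.13. The Schwann cell median was 0.18 (camera adjusted p = 0.0136, and adjusted p = 0.360 with an estimated correlation). The Schwann cell call was lost without 16.5-week replicate 15 (adjusted p = 0.151) and 86-week replicate 12 (0.105). For 7 atrial markers, 0 passed either way, all 7 changes were positive and Myl4, the atrial light chain, was at 1.75 ± 0.86 (3.44 ± 0.55 without 16.5-week replicate 19 and 1.15 ± 0.90 without 16.5-week replicate 15). The atrial median was 1.32 (camera adjusted p = 0.0136, and adjusted p = 0.672 with an estimated correlation). The atrial call was lost without 16.5-week replicates 14 (adjusted p = 0.0715), 15 (0.142) and 20 (0.0501), and 86-week replicates 11 (0.102), 12 (0.0751) and 14 (0.204).

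Camera placed lists of energy metabolism and contraction lower in the aged left ventricle, with 0 members called over all genes by edgeR. Of 79 nuclear-encoded respiratory chain genes 2 had positive changes and 0 passed either way, with Cox7a1, a subunit of cytochrome c oxidase, at -0.34 ± 0.12. The respiratory chain median was -0.14 (camera adjusted p = 5.39e-10, and adjusted p = 0.710 with an estimated correlation). Fatty acid oxidation had 0 of 30 members either way, with Pdk4, a kinase that restrains glucose oxidation, at -1.06 ± 0.29 (-0.70 ± 0.29 without 16.5-week replicate 14). The fatty acid median was -0.16 (camera adjusted p = 2.28e-06, and adjusted p = 0.710 with an estimated correlation). The fatty acid call was lost without 86-week replicate 17 (adjusted p = 0.143). Cardiomyocyte contraction and conduction had 0 of 18 over all genes and 1 adjusted over the list alone, which was lower, with the potassium channel gene Kcnd2 at -0.47 ± 0.12. The contraction median was -0.12 (camera adjusted p = 0.00758, and adjusted p = 0.710 with an estimated correlation). The contraction call was lost without 16.5-week replicates 14 (adjusted p = 0.232) and 20 (0.274), and 86-week replicate 17 (0.447). Fast fibre genes had 0 of 17 over all genes and 1 lower when adjusted over the list alone, with the troponin gene Tnnc2 at -1.66 ± 0.44. In 16.5-week replicate 15 Tnnc2 had 2.81 CPM against at most 0.585 in the other 3 young mice, and Myh4 28.7 against at most 1.85. The change of Tnnc2 was -0.84 ± 0.37 without 16.5-week replicate 15. The fast fibre median was -0.33 (camera adjusted p = 0.0136, and adjusted p = 0.672 with an estimated correlation). The fast fibre call was lost without 16.5-week replicate 15 (adjusted p = 0.478) and 86-week replicates 12 (0.0743) and 17 (0.171). Chaperones and the unfolded protein response had 0 of 26 either way, with Dnajb9, a chaperone of the endoplasmic reticulum, at -0.25 ± 0.11 and Ddit3 at 0.37 ± 0.15 (0.23 ± 0.15 without 86-week replicate 12). The chaperone median was -0.085 (camera adjusted p = 0.0373, and adjusted p = 0.754 with an estimated correlation). The chaperone call was lost without 16.5-week replicates 14 (adjusted p = 0.424) and 20 (0.730), and 86-week replicates 11 (0.304) and 17 (0.637). The other 14 lists did not pass, from interferon-stimulated genes (adjusted p = 0.0805) to mitochondrially encoded genes (adjusted p = 0.988), and in them the IgG2c constant gene Ighg2c alone passed over all genes, with 1.77 ± 0.18 (adjusted p = 1.43e-04). For collagens and extracellular matrix the median was 0.017 while the test pointed down, and for endothelial, cell cycle and mitochondrially encoded genes the median was at or below 0 while the mean and the test pointed up, and the sign of these 3 medians changed with the scaling. In all, camera called 12 of 26 lists, none of them with an estimated correlation, and fry, which tests a list on its own, called 0. Of the 12 lists 4 passed in all 8 fits that each left out 1 mouse, and of the 14 others 8 passed in 1 to 5 of them.

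In skeletal muscle Amy1, the salivary-type amylase, rose from 17.4 ± 1.97 to 50.7 ± 6.65 CPM (log2 change 1.55 ± 0.13, SE, n = 4 per age). Mib1, a ubiquitin ligase that acts on Notch ligands, rose from 138 ± 38.1 to 291 ± 107 CPM (1.05 ± 0.14), and Tppp2, of the tubulin polymerization promoting family, rose from 0.974 ± 0.220 to 2.52 ± 0.728 CPM (1.36 ± 0.19). The IgG2c constant gene Ighg2c rose by 1.80 ± 0.22 log2 units. Plet1os, a noncoding RNA named for the opposite strand of Plet1, fell by 1.44 (SE 0.18) and Klhl23, a kelch-like gene, by 0.89 (SE 0.13) on the log2 scale.

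Here edgeR called 8 of 43711 genes, 6 higher and 2 lower, of which 3 of those higher were immunoglobulin segments. Amy1 had an adjusted p of 5.46e-04, and it passed in all 8 fits that each left out 1 mouse. Mib1 (ENSMUSG00000024294.14, chromosome 18, 10725548 to 10818704, adjusted p = 0.0405), Tppp2 (ENSMUSG00000008813.13, chromosome 14, 51918425 to 51920700, adjusted p = 0.0405), Plet1os (ENSMUSG00000101304.1, chromosome 9, 50488795 to 50507823, adjusted p = 0.0314) and Klhl23 (ENSMUSG00000042155.3, chromosome 2, 69821944 to 69836651, adjusted p = 0.0460) passed in 3, 3, 5 and 2 of them, with highest adjusted p of 0.194, 0.194, 0.1799 and 0.273. The count was 5 without 86-week replicate 11, 1 without 86-week replicate 12, 1 without 16.5-week replicate 15, 14 without 16.5-week replicate 19 and 43 without 16.5-week replicate 20. It was 89 with DESeq2, 10 with limma-voom, both with the filter, 1 when sex was left out of the fit and 25 with all 24 libraries in a single fit. With edgeR and no low-count filter it was 0. There 2722 of 55142 genes had an unadjusted p under 0.05, a share below the 0.05 that chance alone gives.

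Camera placed immune lists higher in aged skeletal muscle. All 22 macrophage markers had positive changes with 0 past the test either way, and Mpeg1, the pore protein perforin-2 of macrophages, was at 0.94 ± 0.30 (0.78 ± 0.33 without 16.5-week replicate 19 and 0.45 ± 0.18 without 86-week replicate 14). The macrophage median was 0.40 (camera adjusted p = 6.45e-05, and adjusted p = 0.522 with an estimated correlation). The macrophage call was lost without 16.5-week replicate 19 (adjusted p = 0.0814) and 86-week replicate 14 (0.0600). Among 16 plasma cell and immunoglobulin constant genes Ighg2c rose over all genes (adjusted p = 0.0314, passing in 4 of the 8 fits that each left out 1 mouse) and 4 rose when adjusted over the list alone. The plasma cell median was 0.42 (camera adjusted p = 2.39e-04, and adjusted p = 0.522 with an estimated correlation). MHC class II presentation had 0 of 10 either way, with H2-DMa at 0.45 ± 0.17. The MHC class II median was 0.48 (camera adjusted p = 0.0127, and adjusted p = 0.522 with an estimated correlation). The MHC class II call was lost without 16.5-week replicates 15 (adjusted p = 0.0804) and 19 (0.0814), and 86-week replicates 12 (0.0673) and 14 (0.228). Complement components had 0 of 14 either way, with C6 at 0.67 ± 0.28 (0.43 ± 0.29 without 86-week replicate 14). The complement median was 0.25 (camera adjusted p = 0.0143, and adjusted p = 0.555 with an estimated correlation). The complement call was lost without 16.5-week replicates 14 (adjusted p = 0.0559), 15 (0.0602) and 19 (0.278), and 86-week replicates 12 (0.0880) and 14 (0.449). T and NK cell markers had 0 of 24 either way, with the T cell receptor gene Trbc1 at 1.18 ± 0.40. The T and NK cell median was 0.22 (camera adjusted p = 0.0214, and adjusted p = 0.522 with an estimated correlation). The T and NK cell call was lost without 16.5-week replicates 14 (adjusted p = 0.229) and 19 (0.204), and 86-week replicates 12 (0.0694) and 14 (0.175). Adipocyte markers had 0 of 18 either way, with the hormone leptin, Lep, at 2.08 ± 0.63 (3.14 ± 0.34 without 16.5-week replicate 20). The adipocyte median was 0.73 (camera adjusted p = 6.00e-04, and adjusted p = 0.538 with an estimated correlation). The adipocyte call was lost without 16.5-week replicate 14 (adjusted p = 0.0971) and 86-week replicate 11 (0.0775). The labels do not say which muscle was sampled, and muscles differ in their fibre types. All 13 slow fibre genes had positive changes and 0 passed either way, with the ventricular and slow light chain Myl3 at 1.53 ± 0.64 (0.26 ± 0.41 without 86-week replicate 17). The slow fibre median was 0.68 (camera adjusted p = 0.0177, and adjusted p = 0.538 with an estimated correlation). The slow fibre call was lost without 16.5-week replicates 15 (adjusted p = 0.0602), 19 (0.213) and 20 (0.0558), and 86-week replicates 12 (0.0880) and 17 (0.458). In the same tissue the cardiac myosin Myh6 was at 302 CPM in 86-week replicate 17 and at most 7.42 CPM in the other mice of that age. Cell cycle and proliferation genes had 0 of 25 either way, with the mitotic kinase gene Bub1 at 1.01 ± 0.27 (1.23 ± 0.27 without 16.5-week replicate 19). The cell cycle median was 0.11 (camera adjusted p = 0.0184, and adjusted p = 0.522 with an estimated correlation). The cell cycle call was lost without 16.5-week replicates 14 (adjusted p = 0.0511), 15 (0.0533) and 19 (0.0988), and 86-week replicates 12 (0.157) and 14 (0.174).

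Matrix, fibre and vascular lists were placed lower by camera in aged skeletal muscle. Of 29 collagens and extracellular matrix genes 0 passed over all genes and 6 fell when adjusted over the list alone, with Col1a1 and Col1a2, the chains of type I collagen, at -1.29 ± 0.26 and -1.07 ± 0.26. The matrix median was -0.38 (camera adjusted p = 4.30e-06, and adjusted p = 0.522 with an estimated correlation). Nuclear-encoded respiratory chain genes had 0 of 79 either way, with Cox7c at -0.39 ± 0.12 (-0.31 ± 0.13 without 16.5-week replicate 14). The respiratory chain median was -0.20 (camera adjusted p = 1.47e-15, and adjusted p = 0.522 with an estimated correlation). Fast fibre genes had 0 of 17 either way, with the calcium store protein Casq1 at -0.34 ± 0.12. The fast fibre median was -0.24 (camera adjusted p = 6.45e-05, and adjusted p = 0.522 with an estimated correlation). Endothelial markers had 0 of 17 either way, with the adhesion gene Esam at -0.46 ± 0.13. The endothelial median was -0.19 (camera adjusted p = 8.57e-05, and adjusted p = 0.522 with an estimated correlation). The endothelial call was lost without 86-week replicate 14 (adjusted p = 0.0600). All 12 smooth muscle and pericyte markers had negative changes, with 0 past the test either way and Rgs5 at -0.41 ± 0.13 (-0.27 ± 0.13 without 16.5-week replicate 20). The smooth muscle median was -0.16 (camera adjusted p = 0.00239, and adjusted p = 0.522 with an estimated correlation). The smooth muscle call was lost without 16.5-week replicate 20 (adjusted p = 0.0582). Immediate early genes had 0 of 19 over all genes and 2 lower when adjusted over the list alone, with the nuclear receptor gene Nr4a1 at -0.76 ± 0.16. The early gene median was -0.20 (camera adjusted p = 2.93e-04, and adjusted p = 0.522 with an estimated correlation). Muscle atrophy and proteolysis genes had 0 of 19 either way, with Mstn, the growth inhibitor myostatin, at -0.49 ± 0.16 (-0.33 ± 0.15 without 16.5-week replicate 19). The atrophy median was -0.12 (camera adjusted p = 0.00129, and adjusted p = 0.522 with an estimated correlation). The atrophy call was lost without 16.5-week replicate 19 (adjusted p = 0.0678) and 86-week replicate 17 (0.339). Cytosolic ribosomal proteins had 0 of 76 either way, with Rps14 at -0.49 ± 0.19 (-0.29 ± 0.15 without 86-week replicate 17). The ribosomal protein median was -0.084 (camera adjusted p = 6.45e-05, and adjusted p = 0.634 with an estimated correlation). The ribosomal protein call was lost without 86-week replicate 17 (adjusted p = 0.477). Circadian clock genes had 0 of 17 either way, with Per1 at -0.71 ± 0.27 (-1.14 ± 0.20 without 86-week replicate 14). The clock median was -0.11 (camera adjusted p = 0.0410, and adjusted p = 0.522 with an estimated correlation). The clock call was lost without 16.5-week replicates 14 (adjusted p = 0.0559), 19 (0.298) and 20 (0.0634), and 86-week replicates 12 (0.0673) and 17 (0.733). The other 9 lists did not pass, from fatty acid oxidation (adjusted p = 0.0675) to senescence and secreted senescence factors (adjusted p = 0.683), and for denervation and neuromuscular junction genes the median was -0.040 while the mean was 0.0082, and the sign of the median of chaperones changed with the scaling. Camera called 17 of 26 lists, none of them with an estimated correlation, fry called 0, and camera called 9 without 16.5-week replicate 19. Of the 17 lists 5 passed in all 8 fits that each left out 1 mouse, and of the 9 others 5 passed in 1 to 4 of them.

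In the kidney Aldh1a1, a dehydrogenase that makes retinoic acid, rose from 10.6 ± 5.99 to 27.5 ± 5.26 CPM (log2 change 1.54 ± 0.22, SE, n = 4 per age), and Npy1r, a receptor for neuropeptide Y, rose from 1.83 ± 0.463 to 5.48 ± 2.40 CPM (1.52 ± 0.21). The complement genes C7 and C4b rose by 1.15 ± 0.18 and 0.94 ± 0.16 log2 units, Cyp27b1, the enzyme that makes active vitamin D, by 1.07 ± 0.18, and Eda2r, a receptor of the tumour necrosis factor family, by 1.06 ± 0.18. Cyp2d12, a cytochrome P450 (1.35 ± 0.20), Ces2h, a carboxylesterase (1.005 ± 0.15), Lilr4b, a leukocyte receptor (0.89 ± 0.15), and Trf, the iron carrier transferrin (0.86 ± 0.13), completed the 10 largest rises. Akr1c18, an aldo-keto reductase that inactivates progesterone, fell by 2.16 on the log2 scale (SE 0.19), from 118 to 30.9 CPM in females and from 9.11 to 1.67 CPM in males (means, n = 2 per age and sex). Acsm3, a medium-chain acyl-CoA synthetase, fell by 1.24 (SE 0.15), from 699.6 to 296 CPM in males and from 6.38 to 2.69 CPM in females. Slc26a4, the anion exchanger pendrin, and Foxi1, a transcription factor of the same intercalated cells, fell by 0.80 each (SE 0.11 and 0.12), and the homeobox gene Hmx2 fell by 1.001 (SE 0.15). The remaining named falls were Tldc2 (-1.30 ± 0.21), the steroid dehydrogenase gene Akr1c14 (-1.03 ± 0.17), the organic anion transporter gene Slc22a26 (-1.02 ± 0.17, and -1.28 ± 0.14 without 86-week replicate 12), Itih2 (-0.95 ± 0.16) and Errfi1, a feedback inhibitor of the epidermal growth factor receptor (-0.88 ± 0.14).

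The kidney had 50 calls by edgeR among 44572 genes, 26 higher and 24 lower at 86 weeks, and 5 of the 26 were immunoglobulin segments. Akr1c18 (ENSMUSG00000021214.14, chromosome 13, 4132615 to 4150654) had an adjusted p of 3.70e-04, Acsm3 (ENSMUSG00000030935.15, chromosome 7, 119760923 to 119787513) of 0.00802, Slc26a4 (ENSMUSG00000020651.8, chromosome 12, 31519827 to 31559969) of 0.0180 and Aldh1a1 (ENSMUSG00000053279.8, chromosome 19, 20492715 to 20643465) of 0.0195, and these 4 passed in all 8 fits that each left out 1 mouse. Of the other 16 named genes Npy1r passed in 6 and the rest in 1 to 4, with Itih2 reaching an adjusted p of 0.151. The count was 27 without 86-week replicate 12, 22 without 86-week replicate 14, 25 without 86-week replicate 17, 19 without 16.5-week replicate 14, 25 without 16.5-week replicate 15 and 23 without 16.5-week replicate 19. It was 231 with DESeq2, 28 with all 24 libraries in a single fit and 1 without a low-count filter. When sex was left out of the fit, edgeR called 0 genes, against 231 for DESeq2 and 54 for limma-voom with sex in the fit. In that edgeR fit 2171 of 44572 genes had an unadjusted p under 0.05, a share below the 0.05 that chance alone gives. With sex in the fit there were 3549. When sex is left out, differences between the sexes count as spread, so the lower share does not speak against age changes.

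**Figure D1:**
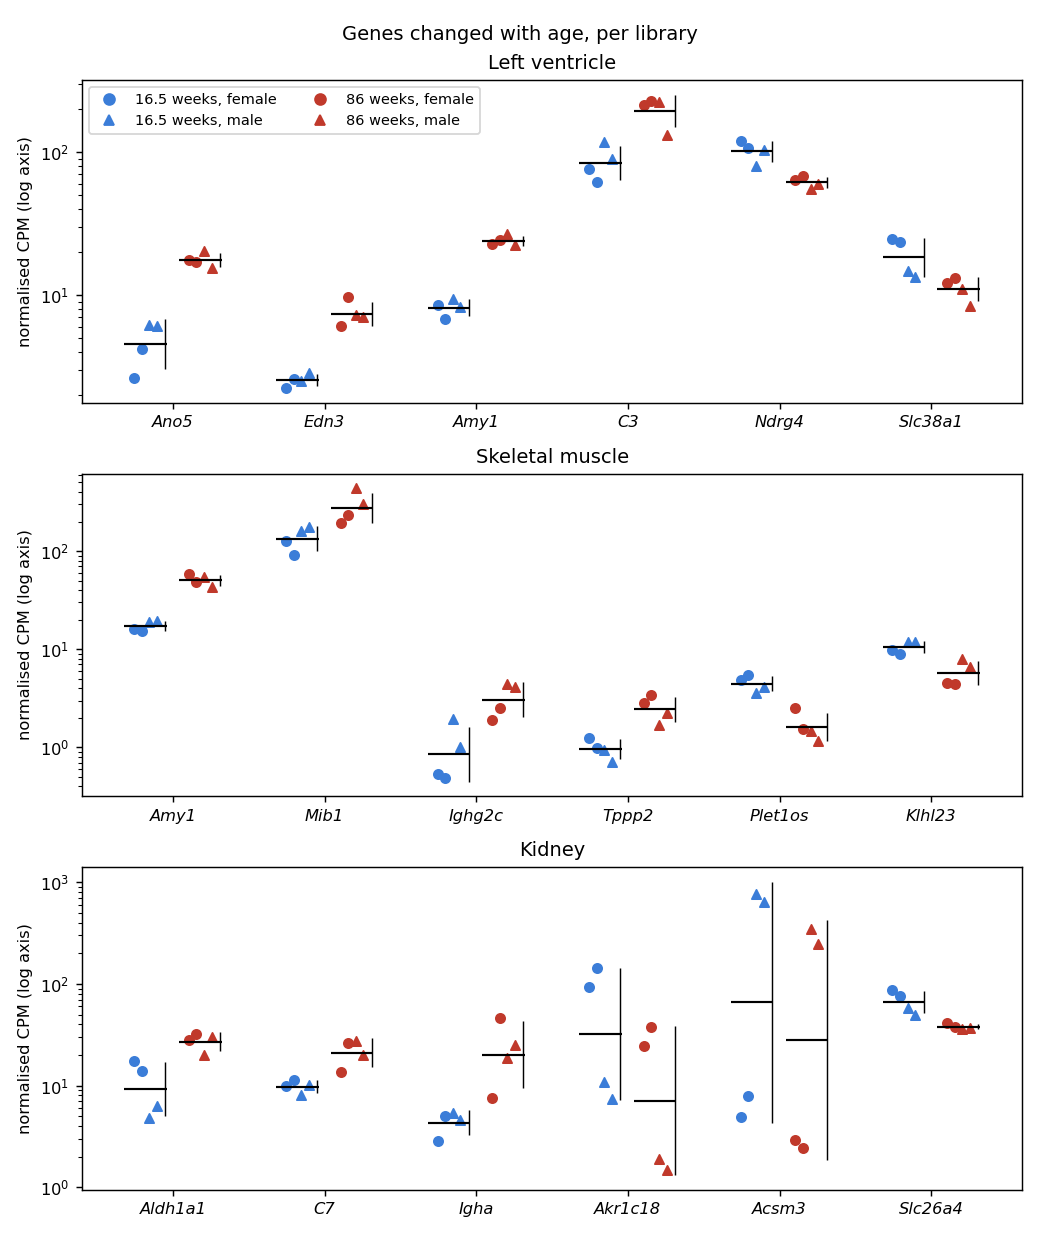
Normalised CPM (log axis) of 6 genes per tissue in each of the 8 mice, with ages by colour and sexes by symbol; horizontal lines are geometric means and vertical lines span 1 SD of the log2 values either way (n = 4). Of the genes drawn for left ventricle Ano5, Edn3, Amy1 and C3 were higher at 86 weeks and Ndrg4 and Slc38a1 lower, and Akr1c18 and Acsm3 in kidney were lower at 86 weeks within each sex.

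In the aged kidney camera placed lists of immune cells higher than other genes. Among 14 complement components C7 (adjusted p = 0.0337) and C4b (adjusted p = 0.0413) rose over all genes, and 10 rose and 1 fell when adjusted over the list alone. The complement median was 0.56 (camera adjusted p = 2.01e-06, and adjusted p = 0.286 with an estimated correlation). None of 22 macrophage markers passed over all genes and 16 rose when adjusted over the list alone, with Aif1 at 0.80 ± 0.16 and the complement subunit C1qa at 0.87 ± 0.18. In 86-week replicate 12 C1qa had 20.7 CPM against at most 11.5 in the other 3 old mice, and its change was 0.64 ± 0.16 without 86-week replicate 12. The macrophage median was 0.61 (camera adjusted p = 6.66e-11, and adjusted p = 0.211 with an estimated correlation). T and NK cell markers had 0 of 25 over all genes and 7 higher when adjusted over the list alone, with the chemokine Ccl5 at 1.19 ± 0.25 and the T cell kinase Lck at 0.76 ± 0.17. The T and NK cell median was 0.58 (camera adjusted p = 4.02e-12, and adjusted p = 0.172 with an estimated correlation). B cell markers had 0 of 14 and 6 in the same order, with the receptor chains Cd79a and Cd79b at 0.74 ± 0.20 and 0.72 ± 0.19. The B cell median was 0.41 (camera adjusted p = 9.49e-05, and adjusted p = 0.172 with an estimated correlation). Igha, the IgA heavy chain constant gene, rose by 2.46 ± 0.40 (adjusted p = 0.0337, passing in 3 of the 8 fits that each left out 1 mouse, and 1.69 ± 0.25 without 86-week replicate 12), 1 of 16 plasma cell and immunoglobulin constant genes over all genes and 1 of 4 when adjusted over the list alone. The plasma cell median was 0.97 (camera adjusted p = 1.12e-05, and adjusted p = 0.460 with an estimated correlation). MHC class II presentation had 0 of 10 over all genes and 7 higher when adjusted over the list alone, with H2-Ab1 at 0.58 ± 0.16 (0.56 ± 0.18 without 16.5-week replicate 19 and 0.33 ± 0.11 without 86-week replicate 12). The MHC class II median was 0.40 (camera adjusted p = 3.08e-05, and adjusted p = 0.286 with an estimated correlation). Interferon-stimulated genes had 0 of 34 over all genes, and 4 higher and 1 lower when adjusted over the list alone, with the transcription factor Irf7 at 0.52 ± 0.12. The interferon median was 0.24 (camera adjusted p = 0.00278, and adjusted p = 0.631 with an estimated correlation). The interferon call was lost without 16.5-week replicate 14 (adjusted p = 0.0561) and 86-week replicates 12 (0.457) and 17 (0.0544).

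Injury, senescence and matrix lists were also placed higher by camera in the aged kidney. Senescence and secreted senescence factors had 0 of 18 over all genes and 4 higher when adjusted over the list alone, with the stress cytokine Gdf15 at 0.82 ± 0.18. The senescence median was 0.26 (camera adjusted p = 0.00109, and adjusted p = 0.172 with an estimated correlation). Tubular injury genes had 0 of 19 over all genes and 5 higher when adjusted over the list alone, with Havcr1, the kidney injury molecule, at 1.45 ± 0.28 (adjusted p = 0.0796). The tubular injury median was 0.17 (camera adjusted p = 0.00547, and adjusted p = 0.521 with an estimated correlation). The tubular injury call was lost without 16.5-week replicate 19 (adjusted p = 0.0744) and 86-week replicates 12 (0.250) and 17 (0.110). Collagens and extracellular matrix had 0 of 29 and 1 in the same order, with the proteoglycan Bgn at 0.56 ± 0.14. Here too 86-week replicate 12 stood apart, with 131 CPM of Bgn against at most 79.2 in the other 3 old mice, and the change of Bgn was 0.43 ± 0.14 without 86-week replicate 12. The matrix median was 0.18 (camera adjusted p = 0.00172, and adjusted p = 0.716 with an estimated correlation). The matrix call was lost without 16.5-week replicate 19 (adjusted p = 0.349) and 86-week replicates 12 (0.1399) and 17 (0.0822). Fry, which tests a list on its own, called 4 lists, T and NK cell markers (adjusted p = 0.0445), male-biased kidney genes (0.0475), B cell markers (0.0138) and senescence factors (0.0138).

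Tubule and energy lists were placed lower by camera in the aged kidney, of which the labels do not give the part sampled. Fatty acid oxidation had 0 of 30 over all genes, and 18 lower and 1 higher when adjusted over the list alone, with Pdk4 at -0.80 ± 0.19 and the peroxisomal enzyme Ehhadh at -0.40 ± 0.11. The fatty acid median was -0.26 (camera adjusted p = 7.04e-11, and adjusted p = 0.211 with an estimated correlation). All 79 nuclear-encoded respiratory chain genes had negative changes and 0 passed either way, with the succinate dehydrogenase gene Sdhc at -0.33 ± 0.10. The respiratory chain median was -0.16 (camera adjusted p = 1.44e-12, and adjusted p = 0.514 with an estimated correlation). Mitochondrially encoded genes had 0 of 13 either way, with mt-Nd3 at -0.25 ± 0.12 (-0.33 ± 0.13 without 16.5-week replicate 15 and -0.13 ± 0.11 without 86-week replicate 14). The mitochondrial median was -0.17 (camera adjusted p = 1.67e-04, and adjusted p = 0.514 with an estimated correlation). Slc26a4 fell over all genes in the list of loop, distal tubule and collecting duct genes, 1 of 20, and 7 fell when adjusted over the list alone. The distal nephron median was -0.23 (camera adjusted p = 1.04e-05, and adjusted p = 0.211 with an estimated correlation). Acsm3 fell over all genes among 12 male-biased kidney genes, and 7 fell and 1 rose when adjusted over the list alone. The male-biased median was -0.39 (camera adjusted p = 3.08e-05, and adjusted p = 0.172 with an estimated correlation). Proximal tubule genes had 0 of 22 over all genes and 1 lower when adjusted over the list alone, with the sodium-proton exchanger Slc9a3 at -0.41 ± 0.10. The proximal tubule median was -0.15 (camera adjusted p = 1.64e-04, and adjusted p = 0.495 with an estimated correlation). Chaperones and the unfolded protein response had 0 of 26 over all genes and 1 lower when adjusted over the list alone, with Herpud1 at -0.53 ± 0.13. The chaperone median was -0.054 (camera adjusted p = 0.0357, and adjusted p = 0.752 with an estimated correlation). The chaperone call was lost without 16.5-week replicates 15 (adjusted p = 0.204) and 20 (0.137), and 86-week replicates 11 (0.722) and 14 (0.384). The other 12 lists did not pass, from endothelial markers (adjusted p = 0.0798) to podocyte genes (adjusted p = 0.944). Signs parted for adipocyte markers (median -0.35, mean 0.029, test down), for smooth muscle and pericyte markers (median 0.039, mean -0.0073, test down) and for cell cycle genes (median 0.028, test down), and the medians of cell cycle and podocyte genes changed sign with the scaling. Camera called 17 of 29 lists, none of them with an estimated correlation. Of the 17 lists 13 passed in all 8 fits that each left out 1 mouse, and of the 12 others 7 passed in 1 to 4 of them.

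**Figure D2:**
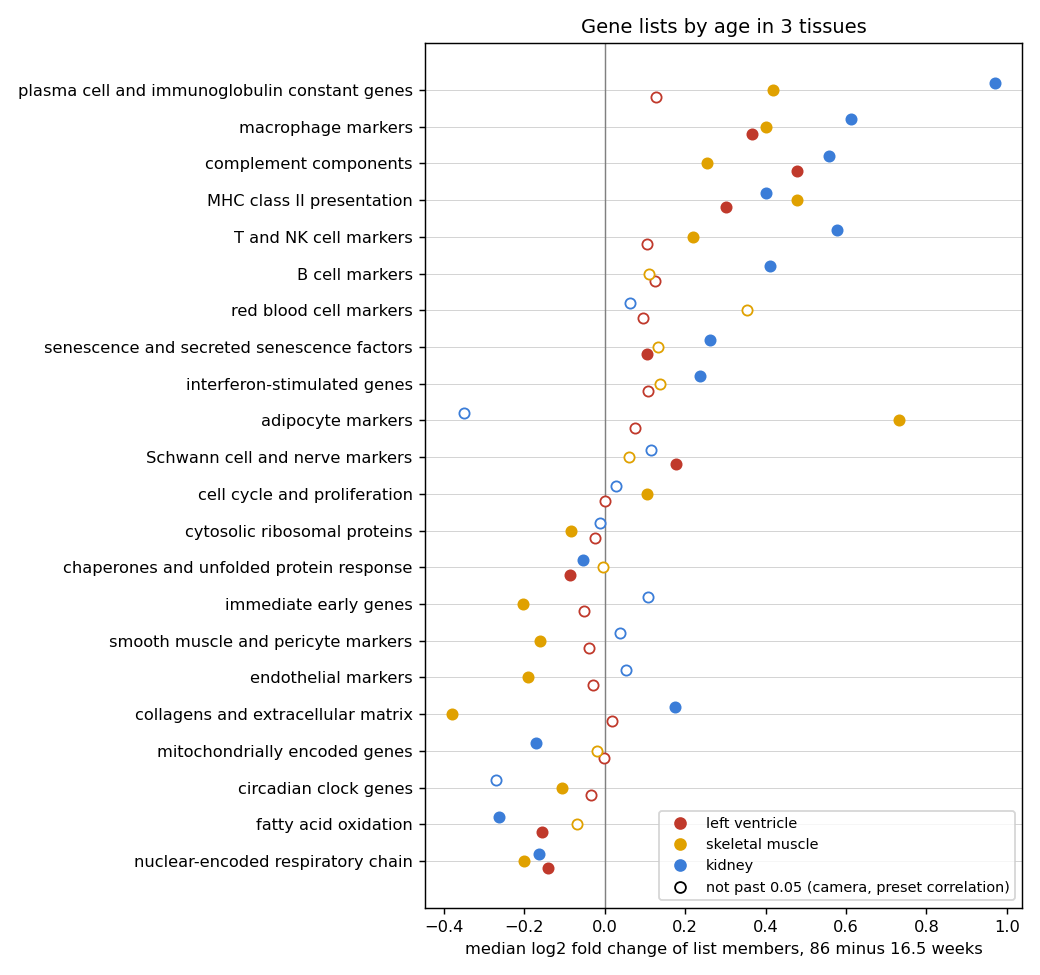
Median log2 change between 16.5 and 86 weeks of the members of 22 gene lists in the 3 tissues (x axis); filled points passed camera at an adjusted p under 0.05 with a preset correlation, open points did not, and none of the filled points passed with an estimated correlation. Macrophage markers had medians of 0.37, 0.40 and 0.61 in left ventricle, skeletal muscle and kidney, and the nuclear-encoded respiratory chain -0.14, -0.20 and -0.16.

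Immunoglobulin segments were summed per library, as CPM without normalisation, since antibody genes differ from mouse to mouse. The permutation tests compared the means of the log2 totals. Their total went from 69.4 ± 51.6 to 309 ± 282 CPM in kidney (n = 4, exact permutation p = 0.0571), from 67.5 ± 34.8 to 140 ± 25.9 CPM in skeletal muscle (exact permutation p = 0.0286, the smallest that 4 against 4 mice allow) and from 31.3 ± 7.46 to 41.4 ± 7.95 CPM in left ventricle (exact permutation p = 0.143, all two-sided). In kidney single mice raised both means: 86-week replicate 12 had 731 CPM and the other 3 old mice 169 ± 25.1 CPM, and 16.5-week replicate 20 had 147 CPM and the other 3 young mice 43.6 ± 2.35 CPM (n = 3). In edgeR 5 of 204 segments rose in kidney, 3 of 149 in skeletal muscle and 1 of 151 in left ventricle, and 0 fell in any of the 3 tissues, where 177, 113 and 103 segments had positive changes. The cell cycle inhibitor genes Cdkn2a and Cdkn1a, which mark senescent cells, did not pass in any tissue: Cdkn2a was at -0.064 ± 0.34, 0.62 ± 0.25 and 0.058 ± 0.27 and Cdkn1a at 0.33 ± 0.20, 0.34 ± 0.21 and 0.99 ± 0.25 in left ventricle, skeletal muscle and kidney, with Cdkn1a in kidney at an adjusted p of 0.235. Over the mice left out Cdkn1a ran from 0.14 to 0.62 in left ventricle and from 0.15 to 0.57 in skeletal muscle.

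Whether the age change itself differed between the 3 tissues was asked next. Ano5 rose by 1.93 ± 0.16 log2 units in left ventricle against -0.35 ± 0.15 in skeletal muscle and -0.041 ± 0.16 in kidney, and Amy1 was at 1.55 ± 0.15, 1.52 ± 0.15 and -0.32 ± 0.16 in the same order (SE, n = 4 per age). Cds1 and Sh3gl2 were at 1.31 ± 0.11 and 1.45 ± 0.19 in left ventricle, and Acsm5, a medium-chain acyl-CoA synthetase, at 1.12 ± 0.15, while their changes in the other tissues lay between -0.32 and 0.15. Mib1 was at 1.02 ± 0.14 and Plet1os at -1.47 ± 0.21 in skeletal muscle, against -0.20 ± 0.14 and 0.71 ± 0.26 in kidney. Akr1c18 was at -2.20 ± 0.21 in kidney and at -0.43 ± 0.29 in left ventricle. The edgeR test of equal age changes passed for 15 of 46984 genes, with adjusted p of 1.53e-05 for Ano5, 4.64e-05 for Cds1, 4.64e-05 for Amy1, 0.00605 for Akr1c18 and 0.0188 for Mib1. With the mouse as a replicate block 20 genes passed, 12 of them shared with the 15, and Sh3gl2 did not (adjusted p = 0.0508). The count was 7 without 86-week replicate 11, 7 without 86-week replicate 12, 26 without 86-week replicate 17, 8 without 16.5-week replicate 14 and 4 without 16.5-week replicate 15, and it was 62 with DESeq2, 7 with RLE size factors, 5 without a low-count filter and 45 with a filter of 1 CPM in 4 libraries.

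**Figure D3:**
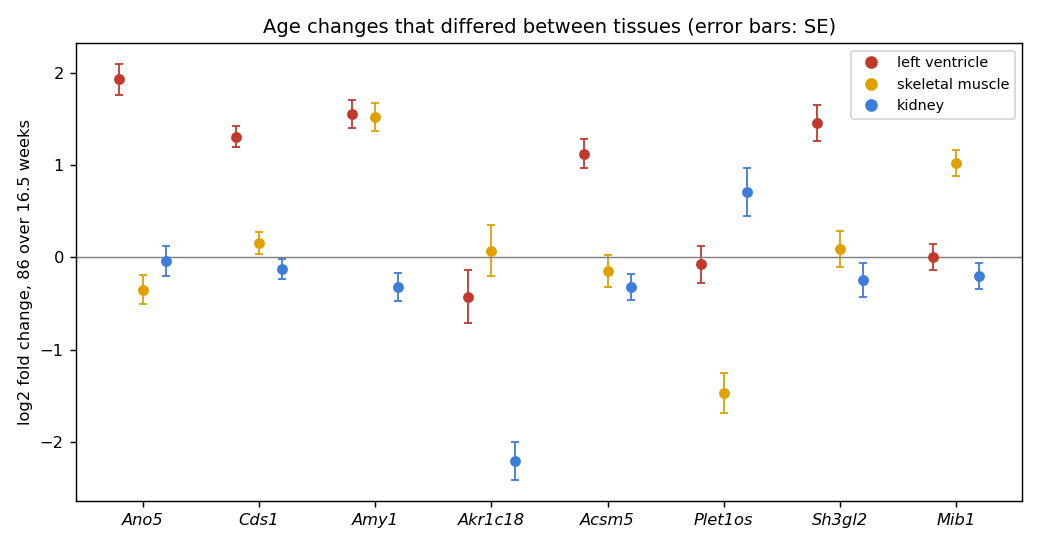
Log2 change between 16.5 and 86 weeks (y axis, error bars 1 SE) of the 8 genes with the smallest p for a difference between tissues, in left ventricle, skeletal muscle and kidney. Ano5 was at 1.93 ± 0.16 in left ventricle and at -0.041 ± 0.16 in kidney.

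Few calls were shared between tissues. Amy1 and Ighg2c were higher at 86 weeks in both left ventricle and skeletal muscle (Fisher's exact one-sided p = 7.14e-06), Ric3, a chaperone of acetylcholine receptors, in left ventricle and kidney (Fisher's exact one-sided p = 0.0172) and the immunoglobulin segment Igkv6-20 in skeletal muscle and kidney (Fisher's exact one-sided p = 0.00365). These 4 genes were named after the overlap was seen, and 0 genes were lower in any pair of tissues. Fisher's test takes the calls of 2 tissues as independent, while the tissues came from the same 8 mice, so these p-values do not allow for what a mouse shares between its tissues. Differences between the 2 mice of an age and sex correlated across genes with mean r of 0.134 between left ventricle and skeletal muscle (-0.0419 to 0.378 over 4 pairs of mice).

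The series holds both sexes, so sex differences were compared within each tissue. In kidney the amino acid transporter gene Slc7a13 was at 1.49 ± 0.410 CPM in females and 629 ± 64.6 CPM in males (log2 difference, males minus females, 8.73 ± 0.16, SE, n = 4 per sex), the organic anion transporter gene Slco1a1 at 8.61 ± 0.26 and the cytochrome P450 gene Cyp2j13 at 7.04 ± 0.12. The glucuronosyltransferase gene Ugt1a2 was at 539 ± 63.4 CPM in females and 2.21 ± 0.935 CPM in males (-7.93 ± 0.25), the growth factor gene Igf2 at -5.57 ± 0.27 and Hdc, the enzyme that makes histamine, at -4.60 ± 0.38. Acsm3 (6.78 ± 0.18), Pzp, a protease inhibitor (6.48 ± 0.18), and Ugt2b37 (6.01 ± 0.20) were higher in males, and the transporters Slc7a12 (-4.88 ± 0.32) and Abcc3 (-4.71 ± 0.16) and the fatty acid hydroxylase gene Cyp4a14 (-4.79 ± 0.28) in females. Slc7a13 (ENSMUSG00000041052.8, chromosome 4, 19818725 to 19842218) had an adjusted p of 8.01e-14 and Ugt1a2 (ENSMUSG00000090171.1, chromosome 1, 88200601 to 88218997) of 4.44e-11. In edgeR 3380 of 44572 genes differed, 1680 higher and 1700 lower in males, of which 2658 were autosomal, 316 X-linked and 308 Y-linked. Of these calls 19, 111 and 301 in the same order were no higher than the 95th percentile of olfactory receptor genes. Adjusted over autosomal genes alone, as was done in all 3 tissues after the counts were seen, 2491 autosomal genes were called, and 1604 without 16.5-week replicate 19.

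In skeletal muscle C7, a terminal complement protein, was at 1.002 ± 0.495 CPM in females and 9.85 ± 5.74 CPM in males (3.27 ± 0.38), the zinc transporter gene Slc30a2 at 3.10 ± 0.21, the matrix gene Npnt at 2.82 ± 0.20 and Amd2, an enzyme of polyamine synthesis, at 2.48 ± 0.25, with Actr3b (2.58 ± 0.38) and the pseudogene Amd-ps3 (2.56 ± 0.25) also higher in males. Lower in males were Socs2, an inhibitor of growth hormone signalling (-1.84 ± 0.28), the cytokine Il15 (-1.68 ± 0.20), the carboxylesterase gene Ces1d (-1.52 ± 0.25), the fatty acid elongase gene Elovl6 (-1.44 ± 0.27), the secreted factor Stc2 (-1.42 ± 0.19) and the nuclear receptor gene Nr4a3 (-1.40 ± 0.31). In edgeR 594 of 43711 genes differed, 427 higher and 167 lower in males, of which 218 were autosomal, 51 X-linked and 310 Y-linked. Of the Y-linked calls 305 were no higher than the 95th percentile of olfactory receptor genes. Adjusted over autosomal genes alone, 118 autosomal genes were called, 72 without 16.5-week replicate 15, 78 without 86-week replicate 14 and 79 to 146 without each other mouse. The count over all genes was 345 without 86-week replicate 12, 918 without a low-count filter, 297 with a filter of 1 CPM in 4 libraries, 1091 with all 24 libraries in a single fit and 208 when genes above that percentile alone were tested.

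In left ventricle C7 was at 4.30 ± 2.37 CPM in females and 16.5 ± 9.06 CPM in males (2.01 ± 0.25) and the aminopeptidase gene Lvrn at 1.13 ± 0.17. The circadian output genes Dbp (2.26 ± 0.45) and Ciart (1.58 ± 0.33) and the methyltransferase gene Inmt (1.21 ± 0.23) were also higher in males. Lower in males were the leucine-rich repeat gene Lrch4 (-0.91 ± 0.19), the RNA-binding protein gene Celf3 (-0.90 ± 0.18), Aldh1a2, an enzyme of retinoic acid synthesis (-0.79 ± 0.18), the matrix gene Olfml2b (-0.73 ± 0.14) and Slc38a1 (-0.58 ± 0.12). Kap, a kidney protein driven by androgens, was at 0.127 ± 0.0719 CPM in females and 3.35 ± 3.69 CPM in males (4.68 ± 0.91) in left ventricle. Single males there ran from 0.202 to 7.40 CPM, and male kidney was at 4657 ± 891 CPM. The kidney gene Umod was at 1.09 ± 0.125 CPM in female and 3.27 ± 2.99 CPM in male left ventricle (n = 4). Whether Kap came from the left ventricle itself or from traces of kidney was not tested. In edgeR 388 of 44546 genes differed, 303 higher and 85 lower in males, and the 281 Y-linked calls included 274 no higher than the 95th percentile of olfactory receptor genes, beside 72 X-linked and 30 autosomal calls. Adjusted over autosomal genes alone 7 were called, fewer than the autosomal genes named in this paragraph, so some of those do not keep the call. Such calls numbered 48 without 86-week replicate 17 and 1 to 4 without each other mouse, and another split of the mice gave 64. The count over all genes was 195 without 86-week replicate 11, 161 without 86-week replicate 12, 213 without 16.5-week replicate 15 and 211 without 16.5-week replicate 19. It was 22 with limma-voom, 18 with a filter of 1 CPM in 4 libraries, 27 when genes above that percentile alone were tested, 725 without a low-count filter and 702 with all 24 libraries in a single fit.

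Whether age acted differently in the sexes was tested by the interaction of age and sex, with 2 mice per age and sex. In kidney Hdc, the enzyme that makes histamine, went from 23.8 to 125 CPM in females and from 2.22 to 2.38 CPM in males (difference of log2 changes, males minus females, -2.29 ± 0.29, SE). Dpys, an enzyme of pyrimidine breakdown, went from 23.4 to 6.86 CPM in females and from 23.3 to 31.4 CPM in males (2.20 ± 0.23), and the transporter gene Slc16a14 differed by 1.29 ± 0.19. Also past the test in kidney were AI506816 (3.16 ± 0.27), and, at no more than the level of olfactory receptor genes, Olfr859 (3.47 ± 0.44), Vmn1r81 (-4.53 ± 0.53) and AC139131.1, which was listed at 0 in young males. In left ventricle Kctd12 was listed at 0 in both old females and had 26.8 CPM in old males and 25.0 CPM in young females, Gpc2 was listed at 0 in old males and had 1.55 CPM in old females, and Olfr539 differed by 4.49 ± 0.50. Listed at 0 in 2 mice of an age and sex were also Gm42878, 1500005C15Rik and Rapgef3os1, and Gal3st4 had at most 1.42 CPM in any age and sex.

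For the interaction edgeR called 11 of 44572 genes in kidney and 7 of 44546 in left ventricle. The log2 age change was higher in males than in females for 7 and lower for 4 in kidney. In left ventricle it was higher for 5 and lower for 2. Of these 7 in left ventricle 4 were listed at 0 in some libraries while others had at least 100 counts. In kidney AI506816 (ENSMUSG00000105987.4, chromosome 5, 23698296 to 23712667) had an adjusted p of 5.32e-04, Dpys (ENSMUSG00000022304.13, chromosome 15, 39768487 to 39857470) of 0.00319 and Hdc (ENSMUSG00000027360.5, chromosome 2, 126593667 to 126619299) of 0.0124. Leaving out a mouse leaves a single mouse in 1 of the 4 cells, which is then assumed to vary like the others. The kidney count was 6 without 86-week replicate 12, 19 without 86-week replicate 14, 32, 31, 33 and 26 without 16.5-week replicates 14, 15, 19 and 20, and Hdc passed in 5 of the 8 fits (highest adjusted p 0.124) and Slc16a14 in 3 (0.1801). The left ventricle count was 13, 23, 33 and 16 without 86-week replicates 11, 12, 14 and 17, and 11, 13, 16 and 23 without 16.5-week replicates 14, 15, 19 and 20. DESeq2 and limma-voom called 35 and 5 genes in kidney and 12 and 1 in left ventricle, and without a low-count filter edgeR called 1 and 2.

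In skeletal muscle edgeR called 0 genes for the interaction, with 2891 at an unadjusted p under 0.05, where DESeq2 called 62 and limma-voom 1. The 5 genes with the smallest p included Ostn, the muscle hormone osteocrin, which went from 3.01 to 89.2 CPM in females and from 4.17 to 13.2 CPM in males (-3.23 ± 0.40, adjusted p = 0.122). The others were Ces1f, a carboxylesterase (-2.77 ± 0.38), Mrps34, a mitochondrial ribosomal protein (-1.89 ± 0.27), and the unnamed loci Gm45234 and 1600017P15Rik, with adjusted p from 0.141 to 0.197. The count was 3, 18 and 12 without 86-week replicates 12, 14 and 17, 1, 15, 47 and 20 without 16.5-week replicates 14, 15, 19 and 20, and 0 without 86-week replicate 11.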

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

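The tests of read-through RNA, of neighbouring genes and of collecting duct and proximal tubule genes were chosen only after the results were seen, and the others before.

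Nearly every annotated gene of every library had counts at a similar low level, and genomic DNA in the libraries is a candidate source. X-linked genes at that level (1128 genes) had a log2 male to female ratio of -0.91 over the mice (pairs of mice -0.94 to -0.88, exact permutation p = 0.0286, two-sided, the smallest possible; left ventricle -0.95, skeletal muscle -0.86, kidney -0.92), and Y-linked ones stood at 0.497 of the autosomal level in males and 0.000728 in females, while 5 highly expressed X genes had a median of -0.087. Unspliced or read-through RNA of the sampled cells as the whole source is argued against by the highest of those pairs, -0.88, since it would leave the ratio above -0.5. As a part of the source beside transcribed genes it stays open, because background genes within 5 kb of kidney-specific genes stood 2.46 times as high as isolated ones (37 genes, 95% bootstrap interval 1.40 to 6.85). The test first written joined the X ratio with the neighbour ratio and came out neither way; it was parted, and kidney chosen for the neighbours, after both values were seen (left ventricle 17.5 and skeletal muscle 22.1 on 3 genes each, mean of 3 tissues 14.04).

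Some genes were listed at 0 in some libraries of a tissue and at 100 counts or more in others, among them the interaction calls Kctd12, Gpc2, Gm42878 and Gal3st4. Reads of overlapping genes given to a single gene by the quantification are a candidate explanation: exons of 79% of these 100 genes overlapped another gene against 25.5% of 1432 matched genes, a ratio of 3.10 (Fisher's exact p = 7.56e-27, two-sided). A switch of expression with age and sex cannot be told apart from random placement, since zeros filled whole age and sex cells in 9 of 158 gene and tissue pairs (7.34 on average by random placement, 95th percentile 12, permutation p = 0.307). Age itself stays open for single genes.

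Genes of intercalated cells, a list that includes called genes such as Slc26a4 and Foxi1, had a median log2 change of -0.48 with age in kidney (7 of 20 fell in edgeR, 19 negative, -0.58 to -0.44 over leaving out each mouse). Less collecting duct in the sampled piece cannot be told apart from a change within intercalated cells, because principal cell genes had a median of -0.21 (14 genes, -0.25 to -0.13), whose range spans 0.5 times the fall. A larger share of RNA from other parts of the nephron cannot be told apart from it either. Proximal tubule genes had a median of -0.15 (-0.23 to -0.075), but as much of kidney RNA comes from proximal tubule, they would hardly rise with such a share. Age-related loss or change of intercalated cells, the biological explanation that the design offers, was not tested.

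A cut-off was used that flags about 1 in 20 groups of independent normal values, or 22.4 of 448 groups. The groups mixed both sexes and genes vary together, so 22.4 need not be what chance gives here. Single libraries lay far from the other 3 of their group in 36 of the 448 groups. In left ventricle at 16.5 weeks these were replicate 20 for Alas2 (8.59 CPM), Slc34a1 (6.43 CPM) and Umod (7.67 CPM), replicate 15 for Cyp2b10 (1.36 CPM), Myh4 (28.7 CPM) and Tnnc2 (2.81 CPM), and replicate 19 for Myl1 (15.1 CPM) and Myl4 (47.2 CPM). At 86 weeks they were replicate 17 for C3 (131 CPM) and Lyz2 (36.1 CPM) and replicate 14 for Rpl37a (54.0 CPM). In skeletal muscle at 16.5 weeks replicate 19 stood apart for Bub1 (0.759 CPM), Mpeg1 (2.73 CPM), Mstn (82.1 CPM), Slc34a1 (12.8 CPM) and Umod (15.5 CPM), replicate 14 for Cox7c (150.0 CPM), replicate 15 for Ddit4 (25.7 CPM) and replicate 20 for Lep (11.05 CPM) and Nppa (0.870 CPM). At 86 weeks it was replicate 14 for C6 (1.52 CPM) and Gpnmb (7.05 CPM), and replicate 17 for Il2rb (3.10 CPM), Myh6 (302 CPM) and olfactory receptor genes (820.2 CPM without normalisation). In kidney at 86 weeks replicate 12 stood apart for Bgn (131 CPM), C1qa (20.7 CPM), Ccl8 (1.46 CPM), Myh6 (32.7 CPM), Pdgfrb (73.8 CPM) and Slc22a26 (20.005 CPM), replicate 11 for Actg2 (0.503 CPM) and replicate 17 for Myh4 (9.26 CPM). At 16.5 weeks it was replicate 19 for H2-Ab1 (63.1 CPM) and Myh4 (12.7 CPM) and replicate 15 for mt-Nd3 (164 CPM).

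The age change differed between the sexes, by the interaction test of edgeR, for 7 named genes in each of left ventricle and kidney. In left ventricle the fitted differences, males minus females on the log2 scale, were 13.86 for Kctd12, 11.31 for Gal3st4, 11.02 for Gm42878, 9.18 for 1500005C15Rik, 4.49 for Olfr539, -8.79 for Gpc2 and -8.30 for Rapgef3os1. Where a group was listed at 0 such a value depends on the prior count and bounds nothing. In kidney they were 9.41 for AC139131.1, 3.47 for Olfr859, 3.16 for AI506816, 2.20 for Dpys, 1.29 for Slc16a14, -2.29 for Hdc and -4.53 for Vmn1r81.

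The age change differed between tissues, by the F-test of edgeR, for 8 named genes, given here in the order left ventricle, skeletal muscle and kidney. The 3 tissues came from the same mice, and with the mouse as a replicate block Sh3gl2 did not pass (adjusted p = 0.0508) while the other 7 did. Log2 changes were 1.93, -0.35 and -0.041 for Ano5, 1.31, 0.15 and -0.13 for Cds1, 1.55, 1.52 and -0.32 for Amy1, and -0.43, 0.071 and -2.20 for Akr1c18. They were 1.12, -0.15 and -0.32 for Acsm5, -0.075, -1.47 and 0.71 for Plet1os, 1.45, 0.092 and -0.25 for Sh3gl2, and 0.0014, 1.02 and -0.20 for Mib1.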

How the results depend on the processing

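The tests on genes above the olfactory receptor level and without genes listed at 0 were chosen only after the results were seen. Where no cause is given, the cause was not tested.

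With DESeq2 the counts were 73 for age in left ventricle, 89 in skeletal muscle and 231 in kidney, 12, 62 and 35 for the interaction, and 62 for the comparison of tissues. With limma-voom they were 22 for sex in left ventricle and 1, 1 and 5 for the interaction in left ventricle, skeletal muscle and kidney. Without a low-count filter they were 18, 0 and 1 for age in the 3 tissues and 725 and 918 for sex in left ventricle and skeletal muscle. They were 2 and 1 for the interaction in left ventricle and kidney, and 5 for the comparison of tissues, all with edgeR. Beside the 0 of skeletal muscle 2722 of 55142 genes had an unadjusted p under 0.05, no more than chance alone gives. There DESeq2 and limma-voom with the filter called 89 and 10. With at least 1 CPM in 4 libraries, which tests fewer genes, the counts were 18 and 297 for sex in left ventricle and skeletal muscle. They were 2 for the interaction in left ventricle and 45 for the comparison of tissues. When genes above the olfactory receptor level alone were tested, they were 27 and 208 for sex in left ventricle and skeletal muscle, where most calls left out were Y-linked, 4 for the interaction in left ventricle and 32 for the comparison of tissues. Without genes listed at 0 the interaction in left ventricle had 2 calls, and 4 of the 7 were such genes. Without sex in the fit, age had 1 call in skeletal muscle and 0 in kidney with edgeR. In kidney 2171 of 44572 genes then had an unadjusted p under 0.05, no more than chance alone gives, against 3549 with sex in the fit. Differences between the sexes count as spread in the fit without sex, so its share does not speak against age changes. With all 24 libraries in a single fit there were 25 calls for age in skeletal muscle, 28 in kidney, 702 for sex in left ventricle and 1091 in skeletal muscle. RLE size factors gave 7 for the comparison of tissues. For gene lists, an estimated correlation gave 0 calls in each tissue, against 12, 17 and 17 with the preset one, and fry gave 0, 0 and 4.

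Over leaving out each mouse the counts ran from 24 to 117 for age in left ventricle, 1 to 43 in skeletal muscle and 19 to 69 in kidney. They ran from 161 to 374, 345 to 718 and 2487 to 3841 for sex, from 11 to 33, 0 to 47 and 6 to 33 for the interaction, from 4 to 26 for the comparison of tissues, and from 8 to 16, 9 to 18 and 15 to 20 for gene lists, with 9 in skeletal muscle without 16.5-week replicate 19. The mouse behind each change over 1.5 times is named with its count beside the result itself. Of the calls, 20 of 33, 1 of 8 and 9 of 50 for age and 144 of 388, 236 of 594 and 2036 of 3380 for sex passed in all 8 fits.

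Values of named genes were repeated with DESeq2, limma-voom, RLE size factors, no low-count filter, no mitochondrially encoded genes and each mouse left out, and not in the other alternatives. Of 265 values 106 were called, of which 56 lost the call in at least 1 of these, 50 in none of these, and 0 changed sign. The kidney calls for age, 0 without sex in the fit, are lost in that alternative. Values not called changed sign in 6 genes and tissues, over ranges across the mice left out. Cdkn2a in left ventricle (-0.32 to 0.23) changed without 86-week replicates 11 (0.099) and 12 (0.052) and 16.5-week replicate 15 (0.23). In kidney (-0.088 to 0.25) it changed without 86-week replicates 11 (-0.042) and 17 (-0.088) and 16.5-week replicate 14 (-0.057). In left ventricle mt-Nd3 (-0.019 to 0.27) changed without 16.5-week replicate 15, mt-Co2 (-0.12 to 0.020) without 16.5-week replicate 14, and Alas2 (-0.017 to 0.39) without 86-week replicate 12. In skeletal muscle mt-Co3 (-0.10 to 0.0012) changed without 16.5-week replicate 19. Libraries held 52602585 to 103797551 counts, and at these depths 61 to 79% of simulated 2-fold changes with age or sex were recovered among genes with a mean of at least 50 counts, but 6 to 21% of those of the interaction.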

Other observations

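The tests of other splits of the mice leave out the split by the other factor, count autosomal genes for sex and ask that a count stay above every other split with any 1 mouse left out, choices made only after the results were seen, as were the correlations and sums given here.

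The 8 mice can be split into 4 and 4 in 35 ways. The split by sex cannot be fitted beside the sex term. Without that term it gave 387 genes in left ventricle, 556 in skeletal muscle, 2905 in kidney and 811 for the comparison of tissues. These counts are differences between the sexes and say nothing about age. The split by sex was left out, and 34 splits were counted. For age in kidney 1 of the 34 splits, the real one, gave as many as 50 genes (highest other 5, and at least 19 with any 1 mouse left out). Splits with unequal numbers of each sex per side overlap with the sex term, so this share does not exclude chance. Nor could chance be excluded in left ventricle (2 splits, 33 genes, highest other 54) or skeletal muscle (2 splits, 8 genes, highest other 78). The same held for the comparison of tissues (2 splits, 15 genes, highest other 36). For gene lists it could not be excluded in left ventricle (13 splits; 12 lists, highest other 20) or kidney (6 splits; 17 lists, highest other 22). In skeletal muscle 1 split, the real one, gave 17 lists, but the highest other gave 16 and the count was 9 without 16.5-week replicate 19, so the splits do not decide. Splits other than by age gave a median of 9, 9 and 12 lists in left ventricle, skeletal muscle and kidney. Of the 34 splits 18 put 2 females and 2 males on each side, as age does, and these alone are too few for a share under 0.05.

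For sex 1 of 34 splits, the real one, gave as many as 388, 594 and 3380 genes in left ventricle, skeletal muscle and kidney (highest others 59, 22 and 1, the split by age left out). Y-linked genes fix that outcome, so these splits decide nothing. Among autosomal genes, adjusted over these alone, 1 split, the real one, gave as many as 118 genes in skeletal muscle (highest other 22, and at least 72 with any 1 mouse left out). In kidney too it was the real split alone (2491 genes, highest other 1, and at least 1604). Splits with unequal numbers of each age per side overlap with the age term, so these shares do not exclude chance. Nor was chance excluded in left ventricle (2 splits, 7 genes, highest other 64). There 48 genes were called without 86-week replicate 17 and 1 to 4 without each other mouse.

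Age changes of 28345 genes correlated between tissues with Pearson's r of 0.160 for left ventricle and skeletal muscle, 0.119 for left ventricle and kidney and 0.183 for skeletal muscle and kidney. Genes are not independent replicates, and the highest r among other sex-balanced splits were 0.313, 0.260 and 0.224 (17 other splits). Differences between the 2 mice of an age and sex correlated across genes between tissues with mean r of 0.134, -0.0238 and 0.00330 in the same order.

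The share of counts from titin, a giant muscle protein, was 6.83% at 16.5 weeks and 6.44% at 86 weeks in left ventricle (exact permutation p = 0.0286, two-sided, the smallest possible, 1 of 18 such measures). The kidney transporter Slc34a1 stood at 4.19 ± 2.05 CPM in male and 1.75 ± 0.772 CPM in female left ventricle (n = 4). Kap stood at 5.47 ± 9.01 CPM in male and 0.591 ± 0.169 CPM in female skeletal muscle, and single males ran from 0.387 to 18.9 CPM.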
